A study of Rattus norvegicus with 8 samples.

How the data were processed

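Total RNA of full-thickness rat skin was amplified and labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. The spot intensities were read from the scanner images with Agilent Feature Extraction 11.0.1.1, per the file headers, while the submitters' processing notes name version 11.0.0.1. The deposited intensity of each spot is Agilent's processed signal, which is background-subtracted and not normalized between arrays, per the file headers. The deposited median spot and median local background intensities, used for 1 alternative, are uncorrected brightness. The flags for spots well above background, saturated or outlying are other values, 0 or 1 per spot, set by the scanner software per the file headers. No normalization between arrays by the authors is recorded in the sources used here.

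Samples were grouped by the treatment in the labels, 4 sham and 4 STZ. Before any fit, all pairs of samples were compared. For probes with at least 3 spots, each spot's deviation from its probe's mean carries the print and hybridisation pattern of 1 array. These deviations, over 7897 spots of brighter probes, correlated at 0.988 or more within 4 pairs (replicates 1 and 3, and 2 and 4, of each group) and at 0.768 or less elsewhere. The header fields gave each pair 1 array position on 1 slide and 2 scans. The rescans were therefore averaged (limma's avearrays) into 4 arrays, 2 per group. The planned fit assumed 8 separate arrays, and it is given as an alternative chosen after the data were seen. With 2 arrays against 2, an exact permutation test could not go below a p of 0.333. Limma's model across all probes, planned beforehand for 8 arrays, was kept. The number of arrays limits the precision of every value.

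Processed signals were taken to log2, the 75th percentile of all 42136 noncontrol spots was subtracted per sample, and the spots of 1 probe were averaged, without spots with an outlier flag. Probes well above background in at least 4 of the 8 samples were kept, 21527 of 24684. STZ was compared with sham by a two-sided moderated test (lmFit and eBayes, limma 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjustment over all tested probes. The p of a gene tests its change on the 75th percentile scale, while printed changes are relative to the median of all tested probes. A probe above background in no sample of a group has only a bound there. Its fold is given as "at least", from the mean of the bright group against the mean over the arrays of the dim group. For each dim array this took the higher of the probe's own signal and the lowest signal among probes well above background. Where the probe's own signal was the higher, as for Il17a, this equals the plain fold and bounds nothing, so its log2 change is given.

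Probes were named by accession through a RefSeq gene table of the rat assembly GRCr8, without versions. It held 14274 of 15323 coding accessions and 20 of 1729 RefSeq noncoding ones, and other probes kept the accession of the files. No coordinates are printed, because the file headers name the older build rn4. The noncoding class rests on the accession prefix alone, and its predicted records are not checked for coding capacity here.

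Gene lists and cell type markers were written before the data were examined, 39 in all. The 37 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with 1 probe per gene (the one with the highest mean signal), among 21158 genes or unnamed transcripts. No call of the 17 held with an estimated correlation, and fry called 1 list, neutrophil (adjusted p = 0.0189). With an estimated correlation, camera takes its p from a t distribution on the 2 residual degrees of freedom, and with the preset one on many more. That test had little power here, so its failures cannot tell whether correlation between genes undoes a call. Fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. The genes named in the text were set beforehand as follows, apart from the exceptions given after. They are the 10 named genes each way past the test whose groups do not overlap (or, as here, with the smallest unadjusted p, said not to pass), 5 noncoding transcripts each way by the same rule, up to 4 members of each list with the smallest p, and MRAK052872 and Plod1. Il1b, Msx2 and Adipoq were chosen after their values were seen. Chrng, Chrnd, Chrna1, Myf5, Cdh15, Myod1, Il36a, Slpi, Plaur, Il1rn, Krt16, Krt17 and Lhx2, from lists added later, were named under no rule set beforehand.

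The fits were tested on simulated data, 10 sets of 21527 probes on 2 arrays per group, each with 200 changed probes and 2 shifted lists of 20 genes. Shares called after adjustment depend on how many probes change, which is unknown in the data, so the shares below need not hold there. Of probes changed by 6 on the log2 scale, 11.8% were called at an adjusted p under 0.05, and none of those changed by 1, 2 or 4, while 4 of 212870 unchanged probes were called. At an unadjusted p under 0.05 the shares were 26.8%, 76.8%, 97.4% and 98.0% for changes of 1, 2, 4 and 6. Camera called all 10 lists of 20 genes shifted by 1 and 1 of 350 unshifted lists, in simulated genes that were independent of each other.

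The alternatives were quantile normalization, normexp with an offset of 50 on the median signals, the percentile over detected probes, other filters on dim probes, a trend and robust estimation, array weights, a replicate block, other thresholds, and each array left out in turn. A slide block was not run, since all arrays shared 1 slide. A scan block has no effect on the averaged arrays, since each was read in both scans, and the scans were also fitted separately. The sham arrays lay at positions 3 and 4 of the slide and the STZ arrays at positions 1 and 2, so position and group cannot be told apart.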

Results

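Full-thickness skin of male Sprague-Dawley rats was profiled on 1-colour Agilent arrays that carry probes for protein-coding and long noncoding transcripts. Rats of 4 weeks were given either streptozotocin (STZ), a toxin of the insulin-producing beta cells of the pancreas, at 60 mg/kg, or sham treatment, and skin was taken 4 weeks later. The labels list 4 sham and 4 STZ samples. The intensity files showed, however, that replicates 1 and 3 of each group, and replicates 2 and 4, were readings of the same array. The log2 intensities of such samples differed with an SD of 0.020 to 0.038, against 0.657 to 0.775 between other samples of a group, and their spot-by-spot deviations correlated at 0.988 to 0.995, against at most 0.768 between other samples. These pairs were counted as 1 sample each, so that every comparison below set 2 sham arrays against 2 STZ arrays (n = 2 per group). Whether an array held RNA of 1 rat or of several is not given in the sources used here. The p-values of single probes therefore rest only on the spread between these arrays, moderated across probes. Each probe's variance was drawn towards a value common to all probes (prior degrees of freedom 3.01, against 2 residual). The SE of a change uses this moderated variance and can exceed what a gene's own SDs would give. A camera p at the preset correlation sets a list's genes against all other genes, taken as nearly independent, and is no measure of the spread between arrays. Among the lists called below, the estimated correlation ran from −0.086 (neutrophil) to 0.903 (MHC class II and antigen presentation). It was 0.573 in the hair shaft and inner root sheath list and 0.053 in that of fatty acid oxidation and ketone metabolism. Lists with an estimate near 0 failed camera with an estimated correlation as well. The labels also speak of a skin wound, and whether the profiled skin had been wounded is not clear from them.

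**Figure D1:**
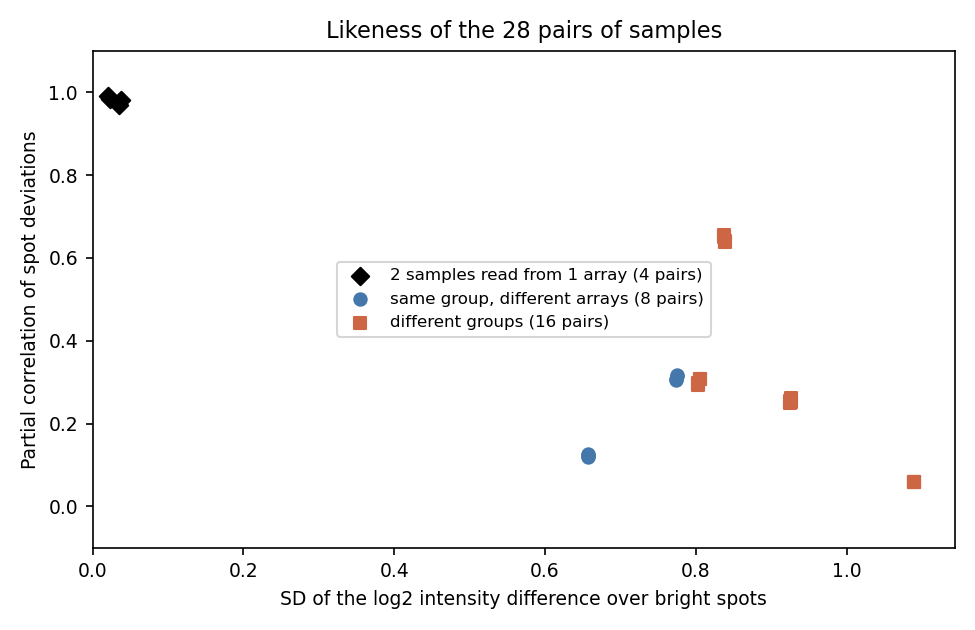
Each point is 1 of the 28 pairs of samples, placed by the SD of the log2 intensity difference over bright spots (horizontal axis) and by the correlation of spot deviations after removal of what the other arrays share (vertical axis). The 4 pairs read from 1 array lie at 0.968 or above on the vertical axis, and all other pairs at 0.654 or below.

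The 75th percentile of spot intensity was 1138 to 1336 in the sham samples, 1481 and 1496 in STZ replicates 1 and 3, and 606 and 624 in STZ replicates 2 and 4. Between 20266 and 22888 of 24684 probes were well above background per sample, most on the array of STZ replicates 2 and 4, and 21527 probes were tested. No spot was saturated. After scaling to the 75th percentile, the median probe was 0.23 higher in STZ on the log2 scale (−0.04 after quantile normalization), so every change of a gene or list below is given relative to that median.

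The first comparison asked how skin of STZ-treated rats differed from skin of sham-treated rats. Genes of inflammation, of macrophages, neutrophils and T and NK cells, and of matrix breakdown were higher in STZ skin, while genes of the hair shaft, of red blood cells and of fat cells were lower. Of 37 gene lists, 9 rose and 8 fell (limma's camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists). None of the 17 was called with an estimated correlation (lowest adjusted p = 0.519), and 1, neutrophil, by limma's fry. The test with an estimated correlation rests on 2 residual degrees of freedom and had little power, so it decides little either way. The median log2 change was 3.05 in the list of inflammatory cytokines and chemokines and −6.16 in that of the hair shaft and inner root sheath. No single probe passed limma's moderated test after adjustment over all 21527 probes, while 1572 were higher and 757 lower at an unadjusted p under 0.05. These counts depended on single arrays, at 5380 and 1094 without the array of STZ replicates 1 and 3, and 677 and 305 without that of sham replicates 2 and 4. The smallest adjusted p was 0.0758, for Defb5, and the changes of single genes below are therefore given as values.

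**Figure D2:**
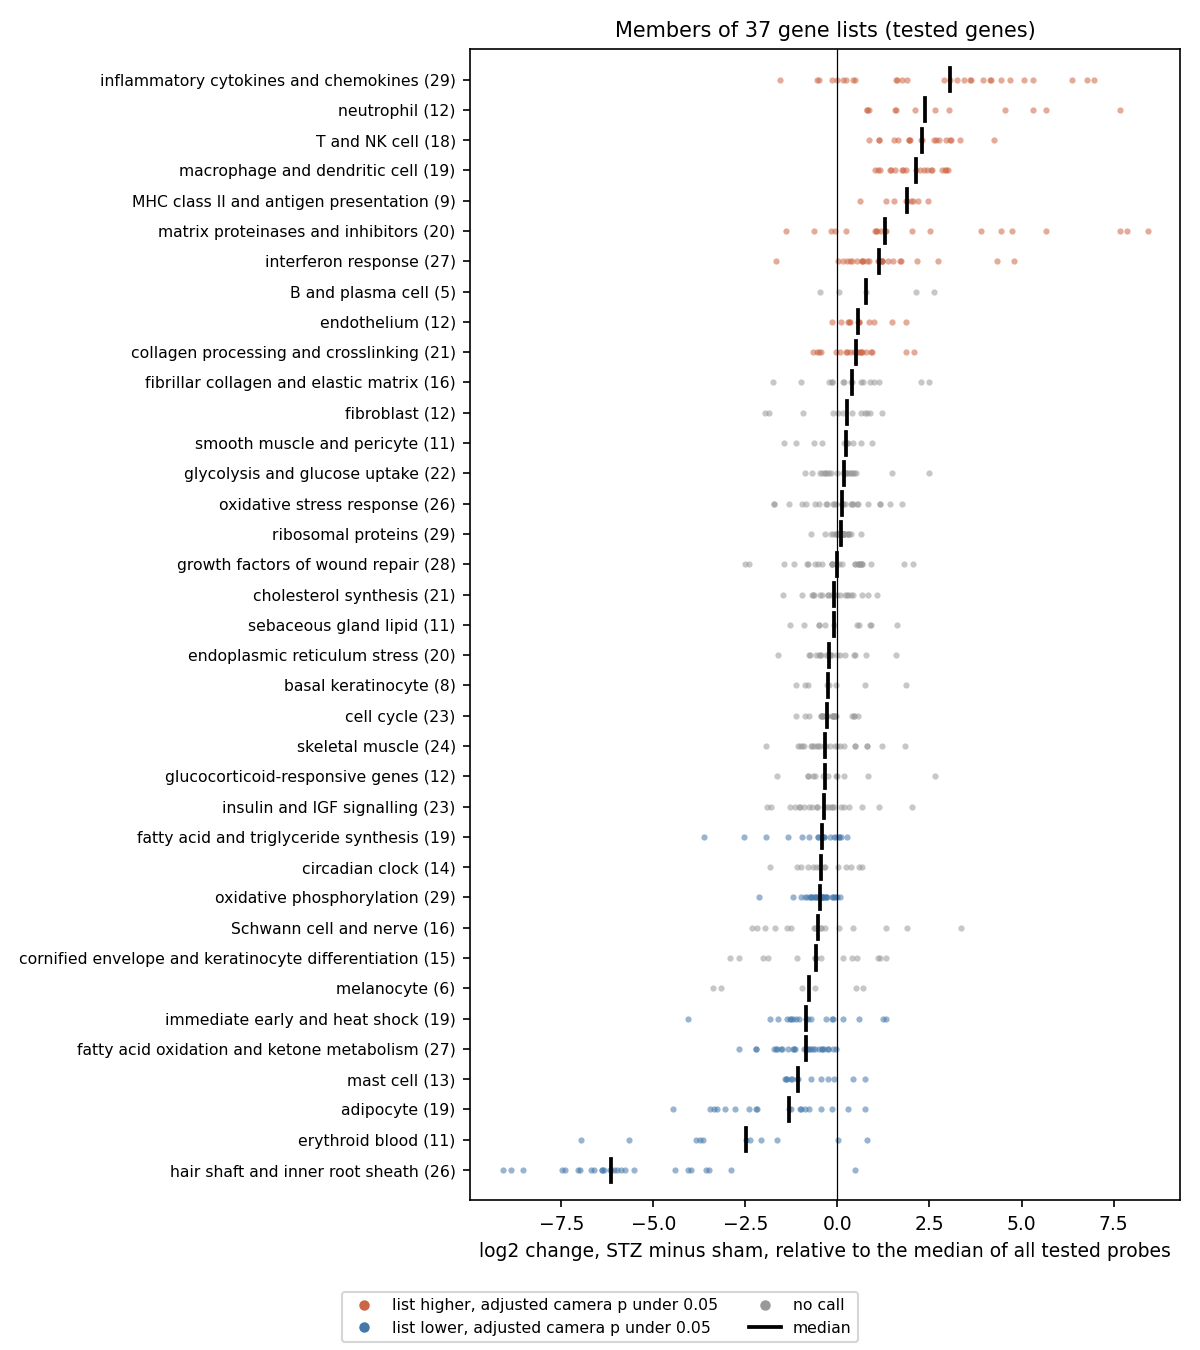
Each point is a tested gene of 1 of the 37 lists, placed by its log2 change between STZ and sham skin relative to the median of all tested probes, with the number of tested genes after each list's name and a black bar at the list's median. The hair shaft and inner root sheath list lies lowest, with a median of −6.16, and the list of inflammatory cytokines and chemokines highest, with a median of 3.05.

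The list of inflammatory cytokines and chemokines rose, with 24 of 29 tested members higher and 17 past the threshold adjusted over the list alone (adjusted camera p = 3.55e-12, and adjusted p = 0.519 with an estimated correlation). Cxcl2, a chemokine that draws neutrophils, had a log2 change of 6.97 ± 0.51 (SE), from −0.89 ± 0.68 in sham to 6.31 ± 0.02 in STZ (SD, n = 2, log2 intensity over the array's 75th percentile). Ccl3, a chemokine of macrophages and T cells, had a change of 6.78 ± 0.52, and the cytokine gene Il1b one of 4.16 ± 0.51. Il17a, a cytokine of T cells, was not well above background in any sham sample. Its log2 change was 3.96 ± 0.42, which rests on its own dim sham signal and is no bound (1.27 after normexp with quantile normalization). Under that setting the list's median was 2.02. The interferon response list also rose, with 26 of 27 members higher and a median of 1.13 (0.67 without the array of sham replicates 2 and 4). In that list 5 members passed adjusted over the list alone, among them Ifit3 (4.80 ± 0.58) and Isg15 (4.33 ± 0.57). Its adjusted camera p was 1.14e-07, and adjusted p = 0.519 with an estimated correlation.

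Markers of macrophages, neutrophils and T and NK cells rose together with these genes, while the B and plasma cell list did not pass and the mast cell list was lower (both below). All 19 tested genes of the macrophage and dendritic cell list were higher, with a median of 2.13, and 18 passed adjusted over the list alone. Fcer1g and Tyrobp, adaptor proteins of myeloid receptors, were higher by 2.96 ± 0.49 and 2.91 ± 0.55 on the log2 scale. All 18 tested genes of the T and NK cell list were higher, with a median of 2.30, and 15 passed adjusted over the list alone. Cd8a, a chain of the coreceptor of cytotoxic T cells, was 4.24 ± 0.42 higher and the granzyme gene Gzma 3.33 ± 0.70 higher. All 12 tested neutrophil genes were higher, with a median of 2.38, and 7 passed adjusted over the list alone. As written, this list shares S100a8 and S100a9 with the inflammatory list and Mmp8 and Mmp9 with the matrix proteinase list. The rises of those lists are therefore not fully separate. S100a8, a subunit of calprotectin, was 5.30 ± 0.42 higher, and Camp, the gene of the antimicrobial peptide cathelicidin, 3.04 ± 0.42 higher. The adjusted camera p was 1.90e-12, 3.55e-12 and 9.46e-09 for these 3 lists, and adjusted p = 0.519 with an estimated correlation for each. All 9 genes of the list of MHC class II and antigen presentation were higher, with a median of 1.88 (1.19 without the array of sham replicates 2 and 4) and 8 past the threshold adjusted over the list alone (adjusted camera p = 1.74e-05, and adjusted p = 0.550 with an estimated correlation). Ctss, a protease that trims the invariant chain, was 2.47 ± 0.56 higher.

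Of the genes with the smallest unadjusted p, the defensins Defb5 and Defb4, antimicrobial peptides of epithelia, stood first. Defb5 was not well above background in any sham sample and was at least 265-fold higher in STZ. Defb4 was 8.94 ± 0.51 higher on the log2 scale, though it was well above background in 3 of the 4 sham samples. Tnfsf11, the gene of RANKL, was at least 9.63-fold higher. The serine protease genes Tmprss11d and Tmprss11g were 5.29 ± 0.44 and 5.62 ± 0.50 higher, and the myeloid lectin gene Clec4d 5.98 ± 0.55 higher (well above background in 3 of the 4 sham samples). After normexp with quantile normalization the log2 changes were smaller, 4.35 for Defb5, 0.71 for Tnfsf11, 3.09 for Tmprss11d, 3.48 for Tmprss11g and 3.33 for Clec4d, so the bounds hold only for the scanner's background-subtracted signals. With all probes of the gene averaged, Tmprss11d was at 3.52. The adjusted p of the 10 named genes higher in STZ ran from 0.0758 to 0.1, and none passed.

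**Figure D3:**
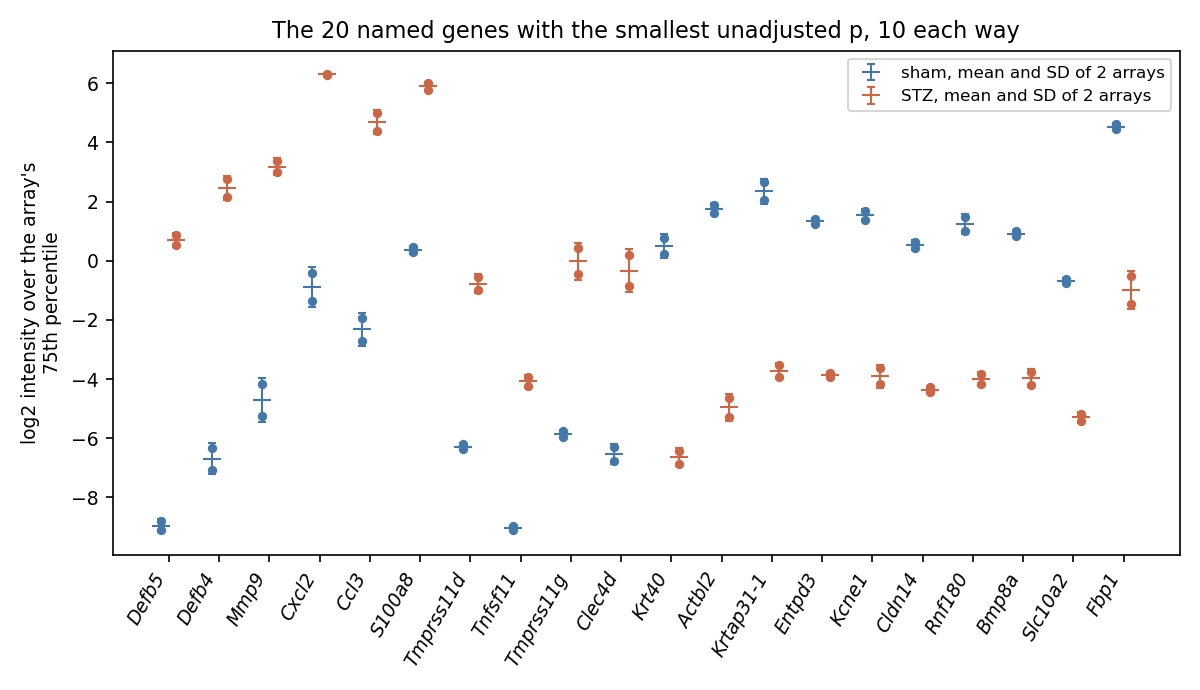
The 20 named genes with the smallest unadjusted p, 10 higher and 10 lower in STZ, are plotted by log2 intensity over the array's 75th percentile, with points for the 2 arrays of each group and bars for mean and SD. Cxcl2 reached 6.31 ± 0.02 in STZ, and Krt40 went from 0.50 ± 0.40 in sham to −6.65 ± 0.31 in STZ, where only 2 of 4 samples were well above background.

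The list of matrix proteinases and inhibitors rose, with 16 of 20 tested members higher, a median of 1.30 and 9 past the threshold adjusted over the list alone (adjusted camera p = 2.09e-06, and adjusted p = 0.519 with an estimated correlation). Mmp9, a gelatinase that neutrophils also release, was 7.67 ± 0.55 higher, Mmp12, the macrophage elastase, 7.87 ± 1.27 higher, and the stromelysin gene Mmp3 4.75 ± 0.81 higher. The list of collagen processing and crosslinking rose by a median of 0.51, with 16 of 21 members higher (adjusted camera p = 0.0489, and adjusted p = 0.853 with an estimated correlation). Without the array of sham replicates 2 and 4 the median was 0.09 (adjusted p = 0.481), and without that of STZ replicates 2 and 4 it was 0.26 (0.218), while after quantile normalization it was 0.88. The call also ended without STZ replicates 1 and 3 (0.0679), with the replicate number as a block (0.101) or crossed between the groups (0.0681), without a filter (0.108), with array weights (0.0654) and in the second scans (0.0519). P4ha3, a subunit of prolyl 4-hydroxylase, and Plod2, a lysyl hydroxylase, passed adjusted over the list alone, with changes of 2.09 ± 0.45 (1.37 after normexp with quantile normalization) and 1.87 ± 0.42. The endothelium list rose by a median of 0.56, with 11 of 12 members higher (adjusted camera p = 0.0153, and adjusted p = 0.550 with an estimated correlation), and none passed adjusted over the list alone. Pdpn, a marker of lymphatic endothelium that basal keratinocytes can also make, was 1.85 ± 0.44 higher and the endothelial adhesion gene Pecam1 0.87 ± 0.43 higher. Without the array of sham replicates 2 and 4 the endothelium list had a median of 0.39 and did not pass (adjusted p = 0.0988), and without that of STZ replicates 2 and 4 its median was 0.23 (adjusted p = 0.0481).

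Genes of the growing hair were the furthest below their sham level. In the hair shaft and inner root sheath list, 25 of 26 tested members were lower and all 25 passed adjusted over the list alone (adjusted camera p = 6.10e-32, and adjusted p = 0.519 with an estimated correlation). Krt28 and Krt72, keratins of the inner root sheath, had log2 changes of −8.87 ± 0.82 and −9.09 ± 0.98. S100a3, a calcium-binding protein of the hair cuticle, had a change of −5.76 ± 0.57, and Msx2, a transcription factor of the hair matrix, one of −3.49 ± 0.45. The list's median was −4.39 without the array of STZ replicates 2 and 4 and −7.93 without that of STZ replicates 1 and 3. The hair keratin gene Krt40 (−7.37 ± 0.47, well above background in 2 of the 4 STZ samples, and −4.32 after normexp with quantile normalization), the keratin-associated protein gene Krtap31-1 (−6.30 ± 0.47) and the actin-like gene Actbl2 (−6.92 ± 0.47) were among the named genes with the smallest unadjusted p. So were Entpd3, an ectonucleotidase (−5.42 ± 0.42), Kcne1, a potassium channel subunit (−5.68 ± 0.46), Cldn14, a tight junction claudin (−5.12 ± 0.42), and Fbp1, an enzyme of gluconeogenesis (−5.74 ± 0.51). The adjusted p of the 10 named genes lower in STZ ran from 0.0873 to 0.102, and none passed.

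Markers of red blood cells and of adipocytes fell alongside the hair genes. The erythroid list had a median of −2.48, with 9 of 11 tested members lower and 8 past the threshold adjusted over the list alone (adjusted camera p = 2.91e-11, and adjusted p = 0.519 with an estimated correlation). Alas2, which starts haem synthesis in erythroid cells, had a change of −5.65 ± 0.61, and the globin gene Hba-a1 one of −3.84 ± 0.52. The adipocyte list had a median of −1.31 (−2.12 over probes well above background in all samples), with 17 of 19 members lower and 8 past the threshold adjusted over the list alone (adjusted camera p = 3.22e-10, and adjusted p = 0.519 with an estimated correlation). Cidec, a lipid droplet protein, had a change of −4.46 ± 0.51, Gpd1, an enzyme that makes glycerol phosphate, one of −3.36 ± 0.48, and Adipoq, the gene of adiponectin, one of −3.04 ± 0.66.

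Of the lists of metabolism, 3 fell as well, by less, while cholesterol synthesis, sebaceous gland lipid and glycolysis did not pass. All 27 genes of fatty acid oxidation and ketone metabolism were lower, with a median of −0.86 (−0.57 after normexp with quantile normalization), though none passed adjusted over the list alone (adjusted camera p = 1.79e-08, and adjusted p = 0.519 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, had a change of −2.22 ± 0.45 (−1.37 after normexp with quantile normalization) and Cpt1a, which admits fatty acids to mitochondria, one of −1.71 ± 0.42. The oxidative phosphorylation list had a median of −0.47, with 27 of 29 members lower and none past the threshold adjusted over the list alone (adjusted camera p = 0.00227, and adjusted p = 0.550 with an estimated correlation). After quantile normalization its median was −0.22 (adjusted p = 0.0487), and after normexp with quantile normalization −0.26. The list of fatty acid and triglyceride synthesis had a median of −0.41, with 15 of 19 members lower (adjusted camera p = 0.00708, and adjusted p = 0.732 with an estimated correlation). Thrsp, a lipogenic gene, had a change of −3.61 ± 0.45 and was the 1 member past the threshold adjusted over the list alone. Its call ended without the array of STZ replicates 2 and 4, where the median turned to 0.18 (adjusted p = 0.965), and without that of sham replicates 2 and 4 (−0.31, 0.0846), while without that of STZ replicates 1 and 3 it was −0.98. After quantile normalization, and after normexp with it, the median was −0.07 and the list did not pass (adjusted p = 0.0949 and 0.147). The immediate early and heat shock list had a median of −0.84 and 15 of 19 members lower (adjusted camera p = 0.00218, and adjusted p = 0.550 with an estimated correlation), and Fos, a transcription factor induced within minutes of a stimulus, had a change of −4.05 ± 0.45. The mast cell list had a median of −1.08, with 11 of 13 members lower (adjusted camera p = 0.00708, and adjusted p = 0.607 with an estimated correlation) and none past the threshold adjusted over the list alone. Without the array of STZ replicates 2 and 4 the immediate early list had a median of −0.52 and did not pass (adjusted p = 0.243), and the mast cell list had one of −0.63 (0.0463). Without the array of sham replicates 1 and 3 the mast cell median was −0.61 (0.369), and after normexp with quantile normalization −0.70 (0.0535), and neither passed.

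The other 20 lists did not pass camera, with adjusted p from 0.0732 upwards. Of these, 11 passed in at least 1 other setting and none in over 3, and those with 3 were Schwann cell and nerve, insulin and IGF signalling, the cornified envelope, and fibrillar collagen and elastic matrix. Among markers of other skin cell types, the medians (and their range with each array left out in turn) were −0.53 for Schwann cell and nerve (−0.83 to −0.33), −0.78 for melanocyte (−1.19 to −0.37), 0.77 for B and plasma cell (0.22 to 1.35), −0.33 for skeletal muscle (−0.58 to −0.01, and past the test without sham replicates 1 and 3), 0.27 for fibroblast (0.09 to 0.65) and 0.22 for smooth muscle and pericyte. Among epidermal and sebaceous lists they were −0.58 for the cornified envelope, −0.26 for the basal keratinocyte list and −0.10 for sebaceous gland lipid. Ivl, the gene of involucrin in the cornified envelope, had a change of −1.89 ± 0.42, and the basal keratin gene Krt14 one of 0.74 ± 0.65. Fibrillar collagen and elastic matrix had a median of 0.39 (0.06 without the array of STZ replicates 2 and 4, and 0.76, past the test at an adjusted p of 0.0285, without that of STZ replicates 1 and 3), cell cycle −0.27, growth factors of wound repair 0.00 and ribosomal proteins 0.10. Insulin and IGF signalling had a median of −0.36 (−0.73 to −0.11 with each array left out), glycolysis and glucose uptake 0.17, cholesterol synthesis −0.09, circadian clock −0.44 (−0.14 after quantile normalization), glucocorticoid-responsive genes −0.33 (−0.08 after it), endoplasmic reticulum stress −0.22 and oxidative stress response 0.13. Trim63, a muscle ubiquitin ligase that insulin signalling holds down, had a change of 2.03 ± 0.64, while 17 of the 23 members of the insulin list were lower, among them Sesn3, a sestrin (−1.80 ± 0.61). The median and the mean differed in sign for the fibroblast list (mean −0.01), the list of smooth muscle and pericyte (−0.06) and the sebaceous list (0.08), and in the smooth muscle and pericyte list camera's direction was downwards against its median.

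Of the probes with an unadjusted p under 0.05 in limma, where about 1076 would be expected by chance, 67.5% were higher in STZ, against 51.8% after quantile normalization and 45.8% after normexp with quantile normalization and 83.1% without the array of STZ replicates 1 and 3. Without the array of sham replicates 2 and 4 the 677 and 305 probes together were fewer than chance would give. With a trend and robust estimation in eBayes, 484 probes were higher and 329 lower at an adjusted p under 0.05. The STZ values lay wholly on 1 side of the sham values for 44.7% of tested probes, and chance gives 33.3%.

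The second comparison asked which long noncoding RNAs differed between STZ and sham skin. More noncoding probes were higher than lower in STZ, by a margin that depended on the scaling and on single arrays. Of 1447 tested probes with a RefSeq noncoding accession, 109 were higher and 14 lower at an unadjusted p under 0.05, where about 72 would be expected by chance. The counts were 79 and 33 after quantile normalization and 46 and 26 after normexp with quantile normalization. Without the array of sham replicates 2 and 4, or without that of STZ replicates 2 and 4, the counts together were no higher than chance would give. The same held after normexp with quantile normalization. Without the array of STZ replicates 1 and 3 the counts were far higher. None passed limma's test after adjustment, and with a trend and robust estimation 12 were higher and 3 lower. The predicted transcripts XR_007207 and XR_008986 were highest by unadjusted p, with log2 changes of 4.25 ± 0.48 and 4.09 ± 0.49 (adjusted p = 0.102 for both), and XR_007207 was at 2.07 after normexp with quantile normalization. XR_007295 and XR_008690 had changes of −2.69 ± 0.57 and −2.34 ± 0.52 (adjusted p = 0.231 and 0.253). XR_007366 had a change of −6.79 ± 1.67, with an SD of 3.55 between the STZ arrays, and was at −4.09 without the array of STZ replicates 2 and 4.

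Among known noncoding RNAs, Gas5 had a change of 0.58 ± 0.54, the imprinted H19 one of 0.39 ± 0.54 and the RNase P RNA Rpph1 one of −0.49 ± 0.87, and their list was too short to test. Of the other 6174 tested transcripts, which carry clone or database names and no class, 389 were higher and 123 lower at an unadjusted p under 0.05, and none passed after adjustment. MRAK160242 had a change of −7.69 ± 0.62 and MRFT38186 one of −6.44 ± 0.43, and BC166774 one of 4.96 ± 0.62. These 3 were chosen after their values were seen. MRAK052872, a transcript that the study's group has taken up as a regulator of the lysyl hydroxylase gene Plod1, was 0.98 ± 0.44 higher in STZ, from −0.97 ± 0.31 to 0.24 ± 0.14 (SD, n = 2; adjusted p = 0.433). Plod1 had a change of 0.53 ± 0.45 (adjusted p = 0.599), which ran from 0.26 to 0.89 over the other settings. This pair was remembered from the group's publication on diabetic rat skin and is no independent evidence of direction.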

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

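The 8-sample fit, the single scans and the crossed pairing were chosen after the data were seen. No probe passed the adjusted threshold in either direction, in either class, under the other normalizations, filters, array weights, the replicate block (0 higher and 0 lower), or the first or second scans alone. A trend with robust estimation in eBayes gave 484 probes higher and 329 lower (noncoding 12 and 3). Taking the 8 deposited samples as independent gave 2992 and 2244 (noncoding 199 and 54), because rescans then count as replicates, and 44.5% of those 5236 probes had an unadjusted p under 0.05 on 4 arrays. An unadjusted p with a 2-fold change gave 1572 and 757 (noncoding 109 and 14). With 1 array left out, the lone array was assumed to vary like the other group, and the counts ran from 0 to 16 higher and 0 to 33 lower (noncoding 0, and 0 to 1), the highest without STZ replicates 1 and 3. The cause of these moves was not tested. A slide block was not run, since all arrays shared 1 slide, nor a scan block, since each averaged array was read in both scans.

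Of the 17 shifted lists, 0 remained called with an estimated correlation and 1 with fry, while other settings called 16 to 21. Apart from these 2 tests, 12 of the 17 were called in every setting, and 5 lost their call in at least 1 (collagen processing, endothelium, mast cell, fatty acid and triglyceride synthesis, and immediate early genes). Replicate numbers did not pair the arrays by any label, and deviations of same-numbered arrays correlated at −0.201 across probes. The replicate block gave 16 lists and the crossed pairing 0 probes and 17 lists. The block ended the call of collagen processing and crosslinking and no other.

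Changes of sign were confined to lists and genes with medians or changes near 0, apart from the left-out arrays below, and their cause was not tested. After quantile normalization Blk was −0.06, and the medians were 0.08 for basal keratinocyte, 0.27 for sebaceous gland lipid, 0.17 for cholesterol synthesis, 0.18 for growth factors of wound repair and 0.10 for endoplasmic reticulum stress. After normexp with quantile normalization the same 6 were −0.08, 0.09, 0.29, 0.24, 0.09 and 0.11, and ribosomal proteins −0.01. Without a filter Blk was −0.10, oxidative stress response −0.02 and ribosomal proteins −0.05. Growth factors of wound repair were at 0.08 over probes detected in all samples and at 0.01 in the second scans.

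With each of the 4 arrays left out in turn, changes ran from −0.04 to 1.90 for Far1, −0.07 to 1.77 for Msmo1, −0.11 to 1.5 for Sqle, −0.13 to 1.56 for Mlana, −0.09 to 1.57 for Krt14, −0.05 to 1.17 for Tpx2, −0.12 to 0.89 for H19, −0.50 to 0.59 for Blk and −1.48 to 0.50 for Rpph1. List medians ran from −1.07 to 0.32 for the cornified envelope, −0.92 to 0.26 for basal keratinocyte, −0.98 to 0.18 for fatty acid and triglyceride synthesis, −0.62 to 0.92 for sebaceous gland lipid, −0.78 to 0.74 for cholesterol synthesis and −0.20 to 0.42 for glycolysis. They ran from −0.76 to 0.19 for cell cycle, −0.15 to 0.02 for growth factors of wound repair, −0.02 to 0.42 for oxidative stress response, −0.65 to 0.15 for endoplasmic reticulum stress, −0.03 to 0.26 for ribosomal proteins and −0.06 to 0.30 for smooth muscle and pericyte. Without STZ replicates 2 and 4, sebaceous gland lipid, glycolysis and cholesterol synthesis (0.74) were called as higher, and melanocyte (−0.59) as lower, while without STZ replicates 1 and 3 cholesterol synthesis (−0.78), the cornified envelope, endoplasmic reticulum stress and insulin and IGF signalling were called as lower and fibrillar collagen as higher. Without sham replicates 1 and 3 cell cycle (−0.76) and skeletal muscle were called as lower, and without sham replicates 2 and 4 the cornified envelope and Schwann cell and nerve. Genes low in 1 group near background have only a bound there.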

Other observations

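Of the tests below, those of the sample pairs, of a single aberrant array and of the follicle share were chosen after their results were seen, and 3 gene lists were added after the main tables but before their own values were seen. A list written for regenerating muscle was higher in STZ skin, with a median log2 change of 1.37 over 13 tested genes and 11 of them higher (camera adjusted over the 3 added lists, p = 8.87e-05, and adjusted p = 0.386 with an estimated correlation). Chrng, the fetal subunit of the acetylcholine receptor, was 4.61 ± 0.58 higher, Chrnd 4.84 ± 0.76 and Chrna1 2.64 ± 0.49. Of the same list, Myf5 (0.54 ± 0.66), Cdh15 (0.04 ± 0.58) and Myod1 (−0.48 ± 0.78) lay within their SE of 0. Whether the rise of the others came from regeneration was not tested. The list of mature skeletal muscle had a median of −0.33. A list of wound-edge keratinocyte genes was also higher, with a median of 1.04 and 13 of 19 genes higher (adjusted p = 0.00427, and adjusted p = 0.412 with an estimated correlation). Its 4 members past the threshold adjusted over the list alone were Slpi, Plaur, Il36a and Il1rn. Whether keratinocytes or other skin cells, such as leukocytes, gave this rise was not tested. Il36a, an epidermal cytokine, was 4.74 ± 0.77 higher, the protease inhibitor gene Slpi 4.47 ± 0.71 and the keratin gene Krt16 2.73 ± 0.81, while Krt17 had a change of −1.54 ± 1.05.

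The macrophage, neutrophil and inflammatory lists were higher and the hair shaft list lower in STZ. These shifts did not rest on 1 STZ array alone. Without STZ replicates 2 and 4 the 4 lists kept at least 0.71 of their medians, and without the other STZ array at least 0.73. Their size did depend on the array, with hair shaft medians of −4.39 and −7.93. The bound was set after these ratios were seen, so they describe the arrays and test nothing. A lower share of follicle tissue alone would let the other cell type lists rise together. The erythroid (−2.48), adipocyte (−1.31) and mast cell (−1.08) lists were lower instead. None of these 3 calls held in camera with an estimated correlation (adjusted p = 0.519, 0.519 and 0.607). That test rests on 2 residual degrees of freedom, and the preset one takes genes as nearly independent, so these lists decide little. Wounded or regenerating skin in the STZ samples is a candidate explanation, since the wound-edge and regenerating muscle lists rose, the lower of their medians being 1.04. Other causes of a rise in these lists were not tested. The labels speak of a wound without saying whether the profiled skin had one. Of these lists, 5 of 19 wound-edge and 1 of 13 muscle genes also stand in lists fixed before. Not all values went this way. The list of growth factors of wound repair, fixed before, had a median of 0.00, with 14 members higher and 14 lower. The cell cycle list had a median of −0.27. In the wound-edge list 6 genes were lower, among them Tgfa (−2.39 ± 0.71) and Krt17 (−1.54 ± 1.05). In the muscle list, with 11 of 13 genes higher, Myf5 (0.54 ± 0.66), Cdh15 (0.04 ± 0.58) and Myod1 (−0.48 ± 0.78) lay within their SE of 0. Another stage of the hair cycle stays open, since the resting follicle and bulge list had a median of −0.45 with 4 members higher and 6 lower (Lhx2 −3.24 ± 0.91). The value lay just inside the bound of −0.5 set beforehand for this stage, and the row was moved from support to undecided after it was seen, because members going both ways decide little. Diabetes itself, different skin sites and different handling of the groups remain open and untested.

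The 8 deposited samples formed 4 near-identical pairs. That each pair is 1 hybridised array read more than once is what the spot deviations show, with a correlation of at least 0.968 in every pair after removal of what the other arrays share. Arrays of 4 separate rats per group are argued against by the SD of log2 differences in a pair, at most 0.058 of that between other samples of the group. Whether files of other arrays were meant for these samples stays open.

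The median of all tested probes was 0.23 higher in STZ after 75th percentile scaling. A compressed signal range on the array of STZ replicates 2 and 4, with the lowest 75th percentile and the most probes above background, is a candidate cause, since without that array the median was 0.03. A true rise of many weakly expressed transcripts on that array was not tested and stays open.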
